A study of Homo sapiens with 28 samples.

How the data were processed

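RNA was sequenced from cortical organoids, free-floating cultures of neural tissue grown from human induced pluripotent stem cells, at days 6, 12, 18 and 30. The 7 cell lines comprised 2 control lines, one named Parental and one named WT in the labels, 3 clones heterozygous for a mutation of CBP (Het clones 1 to 3) and 2 homozygous clones (Homo clones 1 and 2), with 1 library per line and day and 28 libraries in all. CBP is the histone acetyltransferase encoded by CREBBP. The labels do not describe the mutation itself.

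The deposited table holds whole-number read counts per gene and library. Per the labels, polyadenylated RNA was extracted with a column kit (QIAGEN RNeasy Plus) and libraries were made with a stranded kit (KAPA Stranded mRNA-Seq). HISAT2, HTSeq and the hg38 build are named in the submitters' processing notes, and their versions and the strand setting used for counting are not given in the sources used here. Values of antisense and overlapping genes (DLX6-AS1, CCDC144NL-AS1, ZNF667-AS1, B3GALT5-AS1) are therefore uncertain. The same holds for near-identical families whose reads could be divided or discarded in counting, such as ORM1 and ORM2, the chromosome 19 zinc finger genes ZNF98, ZNF257 and ZNF492, and the clustered protocadherins.

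All 58721 gene identifiers matched GENCODE release 29 on hg38, which supplied coordinates, and 41937 of them had a current symbol. The 45 entries for the pseudoautosomal copies on chromosome Y held 0.0015 percent of the counts and were left out, and 14286 genes had no count in any library. The table contained no summary lines of unassigned reads. Library totals ran from 46585281 to 72395665 counts, and 3 counts corresponded to between 0.0414 and 0.0644 CPM (the count scaled to the library total). Mitochondrially encoded genes took 1.285 to 3.179 percent of a library and the 10 most abundant genes 3.96 to 5.63 percent. Counting intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

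The independent unit was the cell line. Parental and WT formed the control group because neither carries a CBP mutation per the labels. The labels do not say whether the WT line went through editing and cloning as the mutant clones did, or whether all lines were differentiated in parallel, so effects of either cannot be told from genotype. For the time course as a whole, the counts of the 4 days were added within each line, giving 7 sums that were compared as Homo with control, Het with control, Homo with Het and any mutant with control. Single days were fitted separately, and the control time course and the difference in the day 6 to day 30 change between genotypes came from 1 fit of all 28 libraries with a group for each genotype and day. Genes were kept by edgeR's expression filter, counts were scaled by TMM, and edgeR's quasi-likelihood test with robust dispersion was applied, with Benjamini-Hochberg adjustment within each comparison and calls at an adjusted p under 0.05. With 1 library per line and day, the p-values rest on the spread between 2 or 3 lines of a genotype, and clones of 1 genotype may share a history that this spread does not show. Pairs of libraries of 1 genotype and day differed by more than counting noise, with a chi-square per degree of freedom of 5.492 to 93.57, so none was treated as a repeat of another.

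The comparisons, alternatives, 40 gene lists and the rule for named genes were chosen before the data were examined. The named genes were those with the largest fold changes among called genes with a mean log2 CPM of at least 1, a gene symbol, and non-overlapping lines: 12 rises and 12 falls for the time-course sums of Homo and of Het against control, and 5 and 5 for each single day and each comparison of days. From a gene list, up to 4 called members with the smallest p were named, and CREBBP and its paralog EP300 were always reported. Genes whose symbol is a clone name and the genes of chromosome Y were left out of the named genes. The lists covered neural, other cell type, pathway and quality-related genes and were tested with limma's camera on log-CPM values (prior count 2, preset correlation 0.01), with adjustment over the lists of a comparison. Lists with fewer than 5 tested members were not tested.

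Alternatives were DESeq2's Wald test, DESeq2-style (RLE) factors in edgeR, no expression filter, 1 fit of all libraries for single days, limma-trend on mean log2 CPM and limma-voom with line as a random block for the time-course sums, the line as a replicate block for comparisons of days, each line left out in turn, a single control line for the overlap of genotypes, and camera with an estimated correlation or fry for lists. Days within a line pair because they come from the same cell line. Over 11914 genes 30 distinct pairs of days within a line had correlations of their deviations from the group means between -0.192 and 0.475, with a median of 0.058, and 12 were above 0.1. Clone numbers do not pair lines of different genotypes. The removal of chromosome X genes and the use of different control lines for the 2 genotypes were added after the data had been seen.

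Where all libraries of a group were at 0 counts, the fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts it is given as a ratio of summed counts per effective library size with an exact 95 percent Poisson interval. Each script that tests many genes was tested on simulated data with the real library sizes and dispersions and 200 changed genes. For Homo against control, the time-course sum recovered 94 of 100 genes changed 2-fold and 98 of 100 changed 4-fold, with 23 unchanged genes called among 25390. The day 6 fit recovered 96 and 100 (25 unchanged called, 18334 genes), the day 30 fit 44 and 90 (12 unchanged called, 20997 genes), and the day 6 to day 30 change 53 and 84 (8 unchanged called, 22198 genes). Set against the calls made, unchanged genes were more frequent in the sum, day 6 and day 30 fits than the adjustment aims for. For the sum, 23 unchanged genes stood beside 94 and 98 recovered ones. Calls near the threshold in these fits are thus less certain than their adjusted p states. The simulated changed list was called in each of the 4 tests and 0 of 20 unchanged lists were called in any. Genes were drawn independently of each other in these simulations. They therefore do not show how often camera calls an unchanged list whose members vary together. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.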

Results

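Gene expression was measured by RNA sequencing in cortical organoids grown from human induced pluripotent stem cells with and without a mutation of CBP, a transcriptional coactivator and histone acetyltransferase encoded by CREBBP. Organoids of 2 control lines (Parental and WT), 3 heterozygous clones (Het) and 2 homozygous clones (Homo) were collected at days 6, 12, 18 and 30, giving 28 libraries with 1 library per line and day. The libraries held between 46585281 and 72395665 counts. The sums of the 4 days held 222732440 to 235306137 counts per line. The design asks how CBP-mutant organoids differ from control organoids over the time course and on each day, whether the 2 genotypes differ, and whether the change from day 6 to day 30 depends on genotype.

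CREBBP was read first, as the mutated gene (ENSG00000005339, protein-coding, hg38 chromosome 16, 3725054 to 3880726). In Parental and WT it stood at 196.2 and 187.2 CPM at day 6, 234.8 and 253.5 at day 12, 147.2 and 158.5 at day 18, and 123.8 and 123.5 at day 30. Het clones 1, 2 and 3 had 172.3, 204.3 and 173.2 CPM at day 6, 224.7, 225 and 229.9 at day 12, 144.4, 160.9 and 150.8 at day 18, and 147.7, 125.5 and 104.8 at day 30. Homo clones 1 and 2 had 156.5 and 186.9 CPM at day 6, 197 and 223.2 at day 12, 118.1 and 154.7 at day 18, and 102.5 and 94.89 at day 30. Over the summed time course CREBBP was lower in Homo by a log2 fold change of -0.23 ± 0.06 (SE, edgeR adjusted p = 0.0463). The Het value of -0.05 ± 0.05 did not pass (adjusted p = 0.743). That CREBBP call was lost with limma-trend (adjusted p = 0.0632) and without Parental (0.107), WT (0.229), Het clones 1, 2 and 3 (0.0923, 0.07 and 0.0639) or Homo clone 1 (0.0783). CREBBP was not called on any single day in either genotype, although it was in Homo at day 12 without the filter on low counts (adjusted p = 0.0136), and at days 12 and 18 without Homo clone 2 (0.023 and 0.0238). Counts per gene cannot show a mutation within a transcript that is still made, so these values neither check nor contradict the genotype labels. EP300, the paralog of CREBBP (ENSG00000100393, chromosome 22, 41091786 to 41180079), was not called in any genotype comparison. Its sum differed from control by -0.05 ± 0.06 in Homo (adjusted p = 0.646) and 0.00 ± 0.05 in Het (adjusted p = 0.993).

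**Figure D1:**
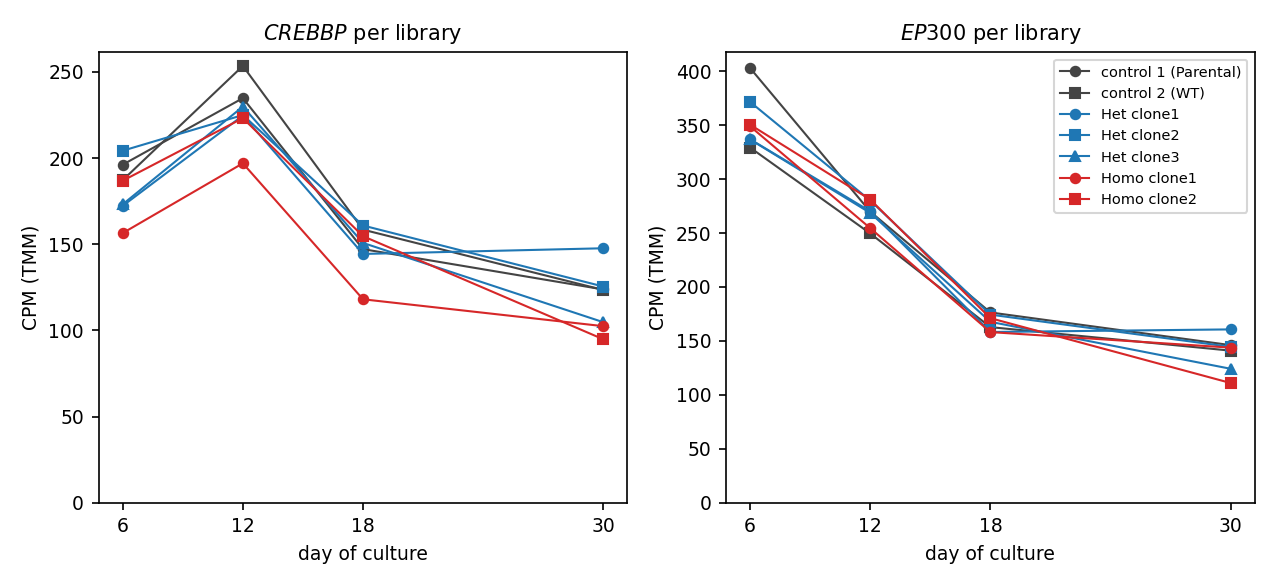
TMM-scaled CPM of CREBBP and EP300 (vertical axes, from 0) against day of culture for each of the 7 lines, 1 point per library, with control lines in grey, Het clones in blue and Homo clones in red. CREBBP lay between 94.89 and 253.5 CPM in all libraries, and both genes were lower at day 30 than at day 6 in every line.

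The control lines described the differentiation itself. Between day 6 and day 30 they lost the pluripotency program and gained radial glia, neurons and cortical markers. All 15 tested pluripotency genes fell (camera adjusted p = 1.62e-08; adjusted p = 0.309 with an estimated correlation), among them TERF1 (-4.02 ± 0.11 on the log2 scale) and DPPA4 (-5.02 ± 0.20). NANOG, a core pluripotency factor, changed by -8.69 ± 0.80, from 306.4 ± 31.8 to 0.765 ± 0.485 CPM (SD, n = 2). Of 15 radial glia genes 14 rose, including SOX9 (3.60 ± 0.15) and the intermediate filament gene VIM (5.05 ± 0.23), with adjusted p = 7.38e-05. This was the only list call of any comparison that held with an estimated correlation (adjusted p = 0.0353). Of 16 pan-neuronal genes 15 rose, including ELAVL4 (8.90 ± 0.28) and the microtubule gene DCX (7.19 ± 0.39; adjusted p = 1.03e-06; adjusted p = 0.275 with an estimated correlation).

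In the same control comparison, 12 of 16 dorsal telencephalon genes rose and 3 fell (adjusted p = 0.000639; adjusted p = 0.309 with an estimated correlation) and PAX6 rose by 4.63 ± 0.36. Of 12 intermediate progenitor genes 11 rose (adjusted p = 7.66e-05; adjusted p = 0.267 with an estimated correlation). The cell cycle list had 19 of 20 members lower (adjusted p = 1.03e-06; adjusted p = 0.309 with an estimated correlation), and 12 of 14 surface ectoderm genes fell (adjusted p = 0.00134; adjusted p = 0.503 with an estimated correlation). Of 21 imprinted genes 19 rose, including the growth factor gene IGF2 (3.11 ± 0.68; list adjusted p = 8.06e-05; adjusted p = 0.267 with an estimated correlation). The counts over the list alone were identical for each of these lists. List medians include members that were at 0 in 1 group: with those at their bound, the median moved from 2.10 to 1.13 for midbrain and hindbrain, from 3.73 to 0.87 for HOX genes and from -0.11 to 0.23 for neuroepithelium. The largest rises by the naming rule started from 0 counts and are lower bounds: at least 3170-fold for DLX6-AS1, 3050-fold for the cortical neuron factor TBR1, 2070-fold for PANTR1, 1950-fold for somatostatin (SST) and 1570-fold for NPR3. The largest falls were at least 325-fold for TNFSF11, at least 231-fold for CYP2B6, -11.70 on the log2 scale for HHLA1, -10.92 for the germline and naive-state gene DPPA3, and a ratio of 1350 (95 percent counting interval 373 to 11200) for KLKB1. CREBBP and EP300 themselves fell by 0.67 and 1.39 on the log2 scale.

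The edgeR test called 16340 of 23540 genes between day 30 and day 6 in controls, 8581 higher and 7759 lower, and all fits that left out 1 line stayed between 13105 and 16873. The median log2 change of all tested genes was 0.124, and 0.182 with DESeq2's scaling, so values are relative to a shift of that size. In a principal component analysis of the 2000 most variable genes, the first component (66.7 percent of the variance) ordered the libraries by day.

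**Figure D2:**
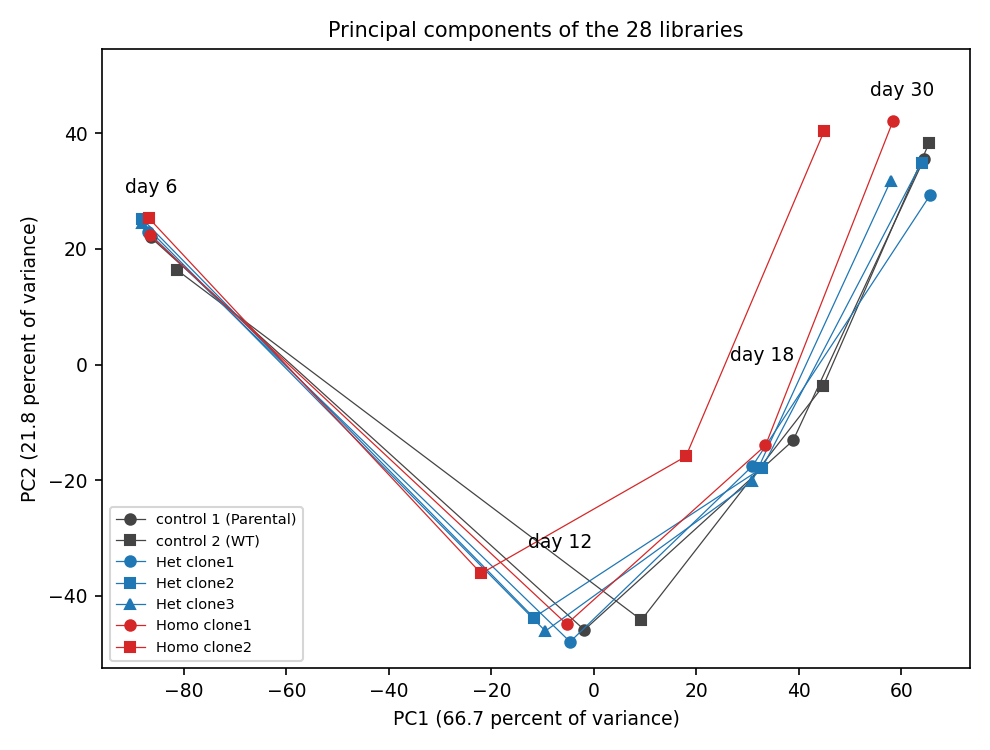
First principal component (horizontal axis, 66.7 percent of variance) against the second (vertical axis, 21.8 percent) for the 28 libraries, with the days of each line joined by a thin line, control lines in grey, Het clones in blue and Homo clones in red. Libraries of 1 day lie together, and Homo clone 2 lies apart from the other lines at days 12, 18 and 30.

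Over the summed time course, homozygous organoids had more mesenchymal, matrix, endothelial and HOX transcripts than controls and had few or no transcripts of a small set of genes. The 4 list calls were made with a preset correlation between genes and were lost otherwise (adjusted p = 0.622 with an estimated correlation). The largest rises were those of the iron carrier transferrin (TF, 4.92 ± 0.91, chromosome 3, 133745956 to 133796640), the connective tissue proteoglycans decorin (DCN, 4.47 ± 0.67, chromosome 12, 91140484 to 91183123) and lumican (LUM, 3.92 ± 0.43, chromosome 12, 91102629 to 91111831), and the collagen gene COL6A3 (4.24 ± 0.76, chromosome 2, 237324003 to 237414375). They were followed by CPED1 (3.86), the endothelial receptor CD93 (3.31), angiotensinogen (AGT, 3.31), A2M (3.25), SERTM2 (3.23), IGSF10 (3.20), the metalloprotease ADAMTS18 (2.98) and the hypoxia factor EPAS1 (2.77 ± 0.38). Up to day 18, TF, LUM and DCN were at or under 0.3065, 1.092 and 0.5228 CPM in the Homo clones. At day 30 Homo clones 1 and 2 had 13.37 and 62.06 CPM of TF, 146.9 and 177.6 of LUM, and 34.14 and 37.42 of DCN. The rises of TF, LUM and DCN in the sums thus came from the day 30 libraries, so their day 30 values are not separate support. The largest falls were those of the zinc finger genes ZNF267 (-9.96 ± 1.1, chromosome 16, 31873758 to 31917357), ZNF98 (-8.36 ± 0.55, chromosome 19, 22391019 to 22532485), ZNF257 (-8.11 ± 0.37, chromosome 19, 22052452 to 22091480) and ZNF492 (-7.05 ± 1.38, chromosome 19, 22634324 to 22667670). CHCHD2, which encodes a mitochondrial protein, fell as far (-8.70 ± 0.40, ENSG00000106153, chromosome 7, 56101569 to 56106576). Smaller falls were measured for TAL1 (-1.95), CCDC144NL-AS1 (-1.85), PCDHGA10 (-1.83), the BMP antagonist CHRDL1 (-1.82) and PPFIA2 (-1.60). Adjusted p lay between 0.000569 (ZNF257) and 0.0494 (CPED1) for the genes named.

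By gene list, 9 of 17 mesenchyme genes rose in Homo and none fell (13 adjusted over the list alone), with a median of 1.66 and camera adjusted p = 5.92e-07. Of 17 targets of BMP, TGF-beta and NODAL signalling 8 rose (15 adjusted over the list alone; adjusted p = 3.29e-07), including ID2 (0.59 ± 0.05), SMAD7 (0.68 ± 0.10) and ID1 (0.96 ± 0.13). HOX genes, which mark posterior identity, had 9 of 21 members higher (17 adjusted over the list alone; adjusted p = 5.92e-07), among them HOXC6 (5.85 ± 1.06), HOXB3 (2.82 ± 0.51) and HOXD13 (2.92 ± 0.42). Of 17 basement membrane and matrix genes 12 rose and 2 fell (13 and 4 adjusted over the list alone; adjusted p = 0.00286). COL4A1 rose by 0.56 ± 0.08, while COL4A5, an X-linked collagen gene, changed by -0.78 ± 0.08. Neural crest genes rose in 6 of 13 cases (9 adjusted over the list alone; adjusted p = 2.14e-05), with TWIST1 at 3.66 ± 0.79 and FOXD3 at 1.73 ± 0.33. Endothelial genes rose in 5 of 11 (9 adjusted over the list alone; adjusted p = 3.7e-05), with FLT1 at 0.62 ± 0.06 and PECAM1 at 2.00 ± 0.41. Surface ectoderm genes rose in 6 of 14 (13 adjusted over the list alone; adjusted p = 4.66e-06), with CDH1 at 0.51 ± 0.07 and KRT18 at 0.95 ± 0.17. Each of these 7 lists had an adjusted p = 0.622 with an estimated correlation.

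Pluripotency genes also stood higher in the Homo sums (adjusted p = 0.00286; adjusted p = 0.635 with an estimated correlation), with 2 of 15 called (6 adjusted over the list alone): NANOG (0.52 ± 0.07) and POU5F1 (0.29 ± 0.06). In every line NANOG was at or above 283.9 CPM at day 6 and at or under 16.67 later. POU5F1 was at or above 1207 CPM at day 6 and at or under 114.6 later. The sums of both genes, in Het as in Homo, thus mostly reflect day 6 and are not separate support for later days. Endoderm genes had 2 of 15 called (8 adjusted over the list alone; adjusted p = 2.86e-05; adjusted p = 0.622 with an estimated correlation), the secreted antagonist CER1 (3.12 ± 0.46) and FOXA2 (2.05 ± 0.44). Choroid plexus and cortical hem genes had 3 of 19 higher (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.00146; adjusted p = 0.622 with an estimated correlation), namely BMP6 (1.15 ± 0.16), AQP1 (1.74 ± 0.27) and FOLR1. On the neural side, 2 of 15 neuroepithelium genes fell (5 adjusted over the list alone; adjusted p = 0.0187; adjusted p = 0.622 with an estimated correlation), SOX1 (-0.92 ± 0.20) and the Notch effector HES5 (-0.83 ± 0.19). Pan-neuronal genes had no called member among 16, also over the list alone, and a list median of -0.46 (adjusted p = 0.0133; adjusted p = 0.7 with an estimated correlation), a call that was lost without WT and without Homo clone 2. Among imprinted genes IGF2 (2.32 ± 0.46) and H19 (2.58 ± 0.52) rose and MEST fell (-0.49 ± 0.06), and the list of 21 was not called (adjusted p = 0.102). The list of 23 acetyltransferases, deacetylases and acetyl readers, to which CBP belongs, was not called either (1 higher and 1 lower, 2 and 3 adjusted over the list alone, adjusted p = 0.413).

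The edgeR test called 2880 of 25902 genes between Homo and control sums, 1832 higher and 1048 lower. The number depended on single lines: it was 908 without Parental, 153 without WT, 727, 1304 and 1303 without Het clones 1, 2 and 3, 6034 without Homo clone 1 and 976 without Homo clone 2. Of the genes named by size, CHCHD2, ZNF98, ZNF257 and CCDC144NL-AS1 kept their calls without each line in turn. Among 952 tested genes of chromosome X, 51 were higher and 94 lower.

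**Figure D3:**
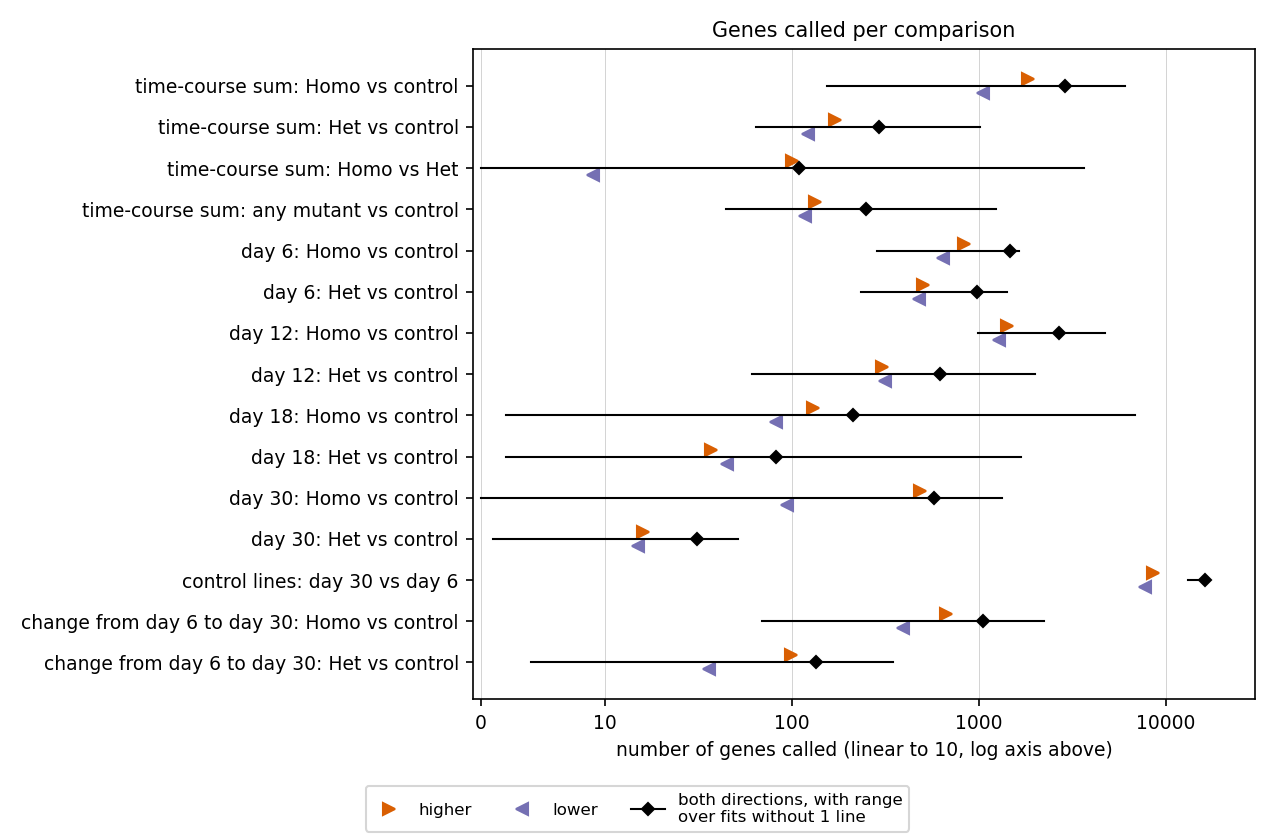
Number of genes called by edgeR at an adjusted p under 0.05 in each of the 15 comparisons (horizontal axis, linear to 10 and logarithmic above), with triangles for genes higher and lower in the first group, diamonds for their sum, and black lines for the range over the fits that left out 1 line. The Homo sums gave 2880 calls with a range of 153 to 6034, and the Het sums 292 with a range of 64 to 1016.

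Heterozygous organoids differed from controls in fewer called genes, and the largest falls were again those of CHCHD2 and the zinc finger genes. CHCHD2 changed by -11.44 ± 0.41 (adjusted p = 0.000531), ZNF267 by -8.54 ± 0.82, ZNF98 by -7.90 ± 0.45 and ZNF257 by -7.10 ± 0.29. Further falls were PCDHGA10 (-2.17), the fibroblast growth factor gene FGF7 (-1.49), CHRDL1 (-1.34), TKTL1 (-1.34), THEM6 (-1.18), skeletal actin (ACTA1, -1.16) and FAM20A (-1.13). Large rises included CDC20B (3.04 ± 0.41), the synaptic organiser CBLN1 (2.26 ± 0.26), the acute phase genes ORM2 (2.02 ± 0.25) and ORM1 (2.01 ± 0.20), CDH13 (1.26), CALHM5 (1.24), the neuregulin receptor ERBB4 (1.17), AACSP1 (1.12), LAMC3 (1.05), the sodium-calcium exchanger SLC8A2 (1.00) and TMEM161B (0.98). BMP, TGF-beta and NODAL targets again stood higher (adjusted p = 0.000455; adjusted p = 0.803 with an estimated correlation), although ID2 (0.45 ± 0.05) was the single called member of 17, also over the list alone. NANOG (0.37 ± 0.06) was the called member of the pluripotency list (2 of 15 adjusted over the list alone; adjusted p = 0.0068; adjusted p = 0.803 with an estimated correlation). The midbrain and hindbrain list had 1 of 20 members higher, GBX2 (0.74 ± 0.12), and 6 adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.803 with an estimated correlation). Endothelial genes (0 of 11 called, 2 adjusted over the list alone; adjusted p = 0.00942) and choroid plexus genes (0 of 19 called, 4 adjusted over the list alone; adjusted p = 0.0177) had positive medians of 0.55 and 0.37, with adjusted p = 0.803 with an estimated correlation for both. COL4A5 changed by -0.74 ± 0.07, close to its value in Homo.

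In all, 292 of 25902 genes were called in Het (edgeR), 170 higher and 122 lower. The count was 91 without WT, 64, 94 and 100 without Het clones 1, 2 and 3, 984 without Homo clone 1 and 1016 without Homo clone 2, the last pair entering through the shared dispersion. The balance turned without WT (35 higher and 56 lower) and without Het clones 1, 2 and 3 (21 and 43, 37 and 57, and 37 and 63). CHCHD2, ORM1, SLC8A2, TMEM161B, ZNF98 and ZNF257 kept their calls without each line. On chromosome X, 8 of 952 genes were higher and 29 lower.

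**Figure D4:**
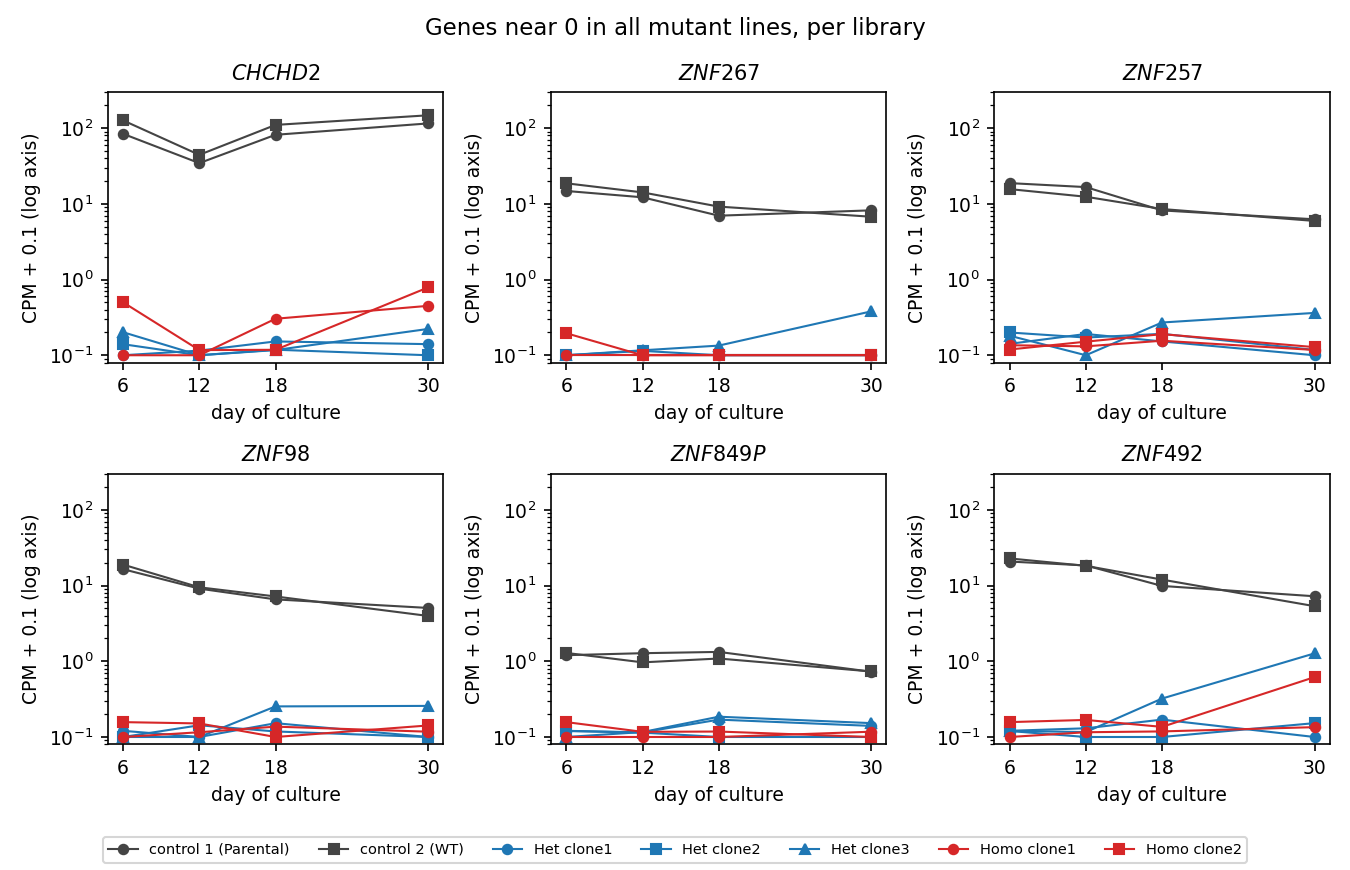
CPM plus 0.1 (vertical axes, logarithmic) against day of culture for 6 genes, 1 point per library, with control lines in grey, Het clones in blue and Homo clones in red. CHCHD2 lay between 34.4 and 148 CPM in the controls and at or under 0.686 CPM in the 20 mutant libraries, and the 5 other genes were likewise lower in all mutant libraries on every day.

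Of the genes tested, 255 were called in both Homo and Het with the same sign (151 higher and 104 lower) and 0 with opposite signs in edgeR, against 12 and 4.94 expected from independent lists of these sizes. Because both comparisons share the control lines, unchanged groups were simulated 20 times, which gave a median of 0 shared genes and at most 2. With no changed gene in the simulation almost none could be called, so this count is no measure for the 255. Counts were drawn independently for each gene and line, so differences that many genes of a control line share were left out. Log2 fold changes of the 2 comparisons over 13857 genes had a Pearson correlation across genes of 0.623 and a covariance of 0.083, against medians of 0.558 and 0.0157 in the simulations. The correlation lay within the simulated range of 0.499 to 0.641, and the covariance above its maximum of 0.0232. Genes are not independent replicates, and the difference in covariance was 0.0673. With Homo set against Parental and Het against WT 88 genes were shared, and 75 the other way round, each with 1 further gene of opposite sign, in an alternative chosen after seeing the data, while WT alone as control gave 288 and Parental alone 68.

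Compared directly, Homo sums exceeded Het sums in lists of non-neural cell types. Endoderm genes had a median of 3.99 with all 15 members higher when adjusted over the list alone, although none of them passed over all genes (camera adjusted p = 1.04e-09). Mesenchyme genes had a median of 1.05 with 14 of 17 higher when adjusted over the list alone and none over all genes (adjusted p = 8.17e-09). HOX genes followed with 12 higher and 1 lower of 21 adjusted over the list alone (adjusted p = 8.13e-06), then neural crest genes with 9 of 13 (adjusted p = 7.96e-06) and BMP, TGF-beta and NODAL targets with 5 of 17 (adjusted p = 1.03e-05). All 5 had an adjusted p = 0.671 with an estimated correlation. The called list members were HOPX (2.65 ± 0.30), BMP6 (1.00 ± 0.14) and FLT1 (0.48 ± 0.06). In edgeR 109 genes were called, 100 higher and 9 lower in Homo (91.7 percent higher, and 72.6 percent of 1533 with DESeq2). The count was 0 without Het clone 1 (2940 genes at an unadjusted p under 0.05), 2 without Het clone 2, 45 without Het clone 3, 3671 without Homo clone 1 and 51 without Homo clone 2.

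With all 5 mutant lines as 1 group, COL4A5 was lower (-0.76 ± 0.06) and ID2 (0.50 ± 0.07), POU5F1 (0.28 ± 0.05), GBX2 (0.76 ± 0.11), the troponin gene TNNT1 (0.65 ± 0.09) and S100A4 (0.85 ± 0.12) were higher than in controls. BMP, TGF-beta and NODAL targets were the list with the smallest p (1 of 17 called, 5 adjusted over the list alone; adjusted p = 2.36e-05; adjusted p = 0.629 with an estimated correlation). Here 250 genes were called by edgeR, 133 higher and 117 lower. Without single lines there were 44 (WT), 81, 127 and 98 (Het clones 1, 2 and 3), 95 (Homo clone 1) and 1231 (Homo clone 2).

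At day 6, when all lines were still rich in pluripotency transcripts, mutant organoids had less PAX6 and more COL6A3, TAGLN and FN1. In Homo, PAX6, a transcription factor of the neural plate, changed by -1.22 ± 0.17 (adjusted p = 0.000913), from 10.0 ± 1.9 CPM in controls to 4.34 ± 0.07 (SD, n = 2 each). Of 13 neuroepithelium genes 1 fell and 1, NES, rose (0.31 ± 0.07), with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0174; adjusted p = 0.492 with an estimated correlation). COL6A3 (2.89 ± 0.38), TAGLN (0.91 ± 0.15) and fibronectin (FN1, 0.86 ± 0.13) were the 3 called of 11 mesenchyme genes (7 adjusted over the list alone; adjusted p = 0.00381; adjusted p = 0.492 with an estimated correlation). Unfolded protein and amino acid response genes had 5 of 14 higher (7 adjusted over the list alone; adjusted p = 0.0224; adjusted p = 0.552 with an estimated correlation), with VLDLR at 0.99 ± 0.14 and SESN2 at 0.70 ± 0.11. The cell cycle inhibitor CDKN1A rose by 1.88 ± 0.38, 1 of 5 called p53 targets of 15, and that list was not called (adjusted p = 0.0697). By size the largest rises were osteopontin (SPP1, 1.96), the histone gene H3C8 (1.88), neurotensin (NTS, 1.80), CHODL (1.78) and D21S2088E (1.63). The largest falls were ZNF492 (3 against 2194 counts, a ratio of 786 with a 95 percent interval of 269 to 3810), ZNF98 (ratio 637, 218 to 3090), ZNF257 (ratio 620, 212 to 3010), CHCHD2 (-9.08) and ZNF267 (-8.43). The edgeR test called 1476 of 18652 genes, 835 higher and 641 lower, with 550 without WT and 283 without Homo clone 2.

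In Het at day 6, PAX6 changed by -0.92 ± 0.15, SOX1, an early neural factor, by -2.28 ± 0.43 and ZIC2 by -0.50 ± 0.09, while NES rose by 0.32 ± 0.07 (3 lower and 1 higher of 13 neuroepithelium genes, 5 and 1 adjusted over the list alone; adjusted p = 0.000919; adjusted p = 0.471 with an estimated correlation). COL6A3 (1.82 ± 0.38), TAGLN (0.67 ± 0.14) and FN1 (0.61 ± 0.12) were among 4 called of 11 mesenchyme genes (7 adjusted over the list alone; adjusted p = 0.000728; adjusted p = 0.471 with an estimated correlation). Among p53 targets 4 of 15 rose (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.0158; adjusted p = 0.471 with an estimated correlation), including the stress cytokine GDF15 (2.43 ± 0.58) and PHLDA3 (0.71 ± 0.17). The immediate early gene JUNB rose by 1.82 ± 0.35, and the keratins KRT18 and KRT8 by 0.65 ± 0.09 and 0.62 ± 0.10. NANOG (0.35 ± 0.06) and POU5F1 (0.23 ± 0.05) were slightly higher than in controls. COL4A5 changed by -1.29 ± 0.09 in Het and -1.34 ± 0.10 in Homo. By size the rises were PCDHGA11 (1.90), D21S2088E (1.73), ZNF667-AS1 (1.5), ORM1 (1.48) and ORM2 (1.38). The falls were ZNF267 (at least 819-fold), ZNF98 (ratio 2600, 466 to 103000), ZNF492 (ratio 1070, 365 to 5190), CHCHD2 (-11.05) and ZNF257 (-7.80). Of 978 genes called by edgeR 500 were higher and 478 lower, and the count was 235 without WT, 417 without Het clone 2 and 238 without Het clone 3. Unlike in Homo, the Het calls of PAX6, COL6A3, TAGLN and FN1 were all lost without WT, those of TAGLN and FN1 also without Het clone 1, FN1 without Het clone 2, and COL6A3, TAGLN and FN1 without Het clone 3.

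At day 12, mutant organoids had less of the neuronal RNA-binding protein gene ELAVL4 and more of the neuronal growth gene STMN2. In Homo the values were -3.43 ± 0.31 for ELAVL4 (adjusted p = 0.000847), 0.86 ± 0.10 for STMN2, 0.56 ± 0.10 for GAP43, and -1.92 ± 0.34 and -2.12 ± 0.38 for the dorsal forebrain factors EMX1 and EMX2. The EMX2 call was lost without Het clone 3 and without either Homo clone. The dorsal telencephalon list thus had 2 members lower and 1, NFIA (0.59 ± 0.14), higher, and the pan-neuronal list 1 lower and 2 higher of 16, and neither list was called. Mitochondrially encoded genes stood higher (2 of 13 called, 7 adjusted over the list alone; adjusted p = 0.0125; adjusted p = 0.962 with an estimated correlation), with MT-CO1 at 0.54 ± 0.07 and MT-ND1 at 0.37 ± 0.08. The pluripotency list was called with none of its 15 members past the threshold over all genes or over the list alone (median 1.03; adjusted p = 0.0125; adjusted p = 0.962 with an estimated correlation). The mesenchymal factor PRRX1 fell (-0.87 ± 0.14) and COL1A1 rose (0.95 ± 0.18), and HOXB3 rose by 2.24 ± 0.57. By size the rises were TCERG1L (4.55), DPPA3 (3.69), SERPINB9 (2.79), the dehydrogenase DHRS2 (2.75 ± 0.32) and ABHD12B (2.70). The falls were ZNF267 (at least 537-fold), CHCHD2 (1 against 4931 counts, ratio 4840, 869 to 191000), ZNF492 (-8.74), ZNF257 (-8.40) and ZNF98 (-8.06). In edgeR 2686 of 19951 genes were called, 1407 higher and 1279 lower. The count was 1765 without Parental, 1010 without WT, 1444, 1318 and 1159 without Het clones 1, 2 and 3, 4731 without Homo clone 1 and 985 without Homo clone 2.

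In Het at day 12, ELAVL4 changed by -2.48 ± 0.25, STMN2 by 0.79 ± 0.09, GAP43 by 0.49 ± 0.09, EMX2 by -1.96 ± 0.33, SOX9 by -0.48 ± 0.06 and PRRX1 by -0.79 ± 0.12. The call was lost without any 1 of the Het clones for GAP43 and EMX2, without WT for GAP43, and without either Homo clone for EMX2. SOX9 and PRRX1 did not keep their calls without each line either, while ELAVL4 and STMN2 did. MT-CO1 rose by 0.34 ± 0.07, 1 of 2 called of 13 mitochondrially encoded genes, with 12 adjusted over the list alone (adjusted p = 7.11e-05; adjusted p = 0.989 with an estimated correlation). DHRS2 (2.48 ± 0.31), ORM1 (2.44), ORM2 (2.30), PRKCH (1.92) and TBX10 (1.83) rose most. CHCHD2 (ratio 7780, 1400 to 308000), ZNF267 (ratio 1290, 358 to 10700), ZNF492 (ratio 1200, 411 to 5840), ZNF98 (ratio 607, 207 to 2950) and ZNF257 (-7.98) fell most. The 618 calls (edgeR, 303 higher and 315 lower) became 173 without WT, 109, 71 and 61 without Het clones 1, 2 and 3, 1923 without Homo clone 1 and 1988 without Homo clone 2.

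At day 18, pluripotency transcripts were higher in both mutant genotypes. In Homo, NANOG stood at 5.25 ± 3.03 CPM (SD, n = 2) against 0.374 ± 0.079 in controls, a log2 fold change of 3.79 ± 0.47 (adjusted p = 0.0305), and TDGF1, a co-receptor in NODAL signalling, rose by 2.13 ± 0.33. These were the 2 called of 15 pluripotency genes, 14 of which were higher when adjusted over the list alone (median 2.13; camera adjusted p = 1.59e-07; adjusted p = 0.51 with an estimated correlation). Neural crest genes had none called of 13 and all 13 higher adjusted over the list alone (adjusted p = 1.48e-06; adjusted p = 0.51 with an estimated correlation). Pan-neuronal genes were lower (1 of 16 called, 10 adjusted over the list alone; adjusted p = 0.000163; adjusted p = 0.51 with an estimated correlation). The called member was ELAVL4 (-1.49 ± 0.24). Intermediate progenitor genes were lower too (1 of 12 called, 7 adjusted over the list alone; adjusted p = 0.000918; adjusted p = 0.51 with an estimated correlation). The called member was NHLH2 (-1.89 ± 0.28), and the neurogenic factor NEUROD1 changed by -1.35 ± 0.22. The p53 targets GDF15 (-2.35 ± 0.35), CDKN1A (-0.97 ± 0.14) and ZMAT3 (-0.79 ± 0.11) fell (3 of 15, also over the list alone; adjusted p = 0.00625; adjusted p = 0.521 with an estimated correlation). By size the rises were DPPA3 (705 against 2 counts, ratio 402, 111 to 3320), ERVH48-1 (4.45), ORM2 (4.05), the ion channel gene TRPV4 (3.85) and NANOG. The falls were ZNF267 (at least 290-fold), ZNF492 (ratio 394, 135 to 1910), ZNF98 (ratio 370, 102 to 3060), CHCHD2 (-9.75) and ZNF257 (-6.79). In edgeR 212 of 20301 genes were called, 130 higher and 82 lower (4863 at an unadjusted p under 0.05). That number was 36 without Parental, 4 without WT, 2, 3 and 4 without Het clones 1, 2 and 3, 6856 without Homo clone 1 and 766 without Homo clone 2, so that CHCHD2 and ZNF257 alone of the named genes kept their calls throughout.

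In Het at day 18, NANOG rose by 3.44 ± 0.45 (adjusted p = 0.0316), to 4.15 ± 0.70 CPM (SD, n = 3), as the 1 called pluripotency gene of 15, with 12 adjusted over the list alone (adjusted p = 4.37e-09; adjusted p = 0.437 with an estimated correlation). Endothelial genes rose in 3 of 11 cases, with 8 adjusted over the list alone and a median of 2.44 (adjusted p = 4.37e-09; adjusted p = 0.437 with an estimated correlation). The 3 were the junction genes CDH5 (2.60 ± 0.27), PECAM1 (2.44 ± 0.25) and ESAM (2.22 ± 0.32). CDKN1A (-1.44 ± 0.13), GDF15 (-2.19 ± 0.30) and ZMAT3 (-0.68 ± 0.10) fell as in Homo (3 of 15 p53 targets, also over the list alone; adjusted p = 0.000528; adjusted p = 0.437 with an estimated correlation). The interneuron genes GAD2 (4.06 ± 0.55) and DLX6 (3.52 ± 0.49) rose, while their list, ventral telencephalon, was not called (adjusted p = 0.306). Further large rises were the growth factor gene FGF19 (3.20) and NKX1-2 (2.72). The largest falls were ZNF267 (ratio 677, 187 to 5590), CHCHD2 (-11.59), ZNF492 (-6.75), ZNF98 (-6.45) and ZNF257 (-6.28). Of the 82 calls (edgeR) 37 were higher and 45 lower, against 534 higher and 306 lower (63.6 percent higher) with DESeq2. Without Parental 207 genes were called, without WT 3, without Het clones 1, 2 and 3 there were 2, 4 and 4, and without Homo clones 1 and 2 there were 1664 and 1691.

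At day 30, homozygous organoids held more transcripts of mesenchyme, basement membrane, cortical hem and choroid plexus than controls and less PAX6. LUM stood at 162.3 ± 21.7 CPM (SD, n = 2) in Homo and 11.9 ± 6.0 in controls (3.82 ± 0.38 on the log2 scale, adjusted p = 0.0264), and DCN (4.41 ± 0.61), COL6A3 (4.21 ± 0.60) and PDGFRB (1.57 ± 0.20) rose with it. In total 8 of 17 mesenchyme genes rose, 14 adjusted over the list alone (median 1.80; camera adjusted p = 5.7e-09; adjusted p = 0.369 with an estimated correlation). Of 17 basement membrane and matrix genes 11 rose, 12 adjusted over the list alone (adjusted p = 4.75e-07; adjusted p = 0.38 with an estimated correlation), including COL5A1 (2.21 ± 0.29), LAMB1 (1.95 ± 0.28) and NID1 (1.80 ± 0.25). Choroid plexus and hem genes rose in 6 of 19 cases, 12 adjusted over the list alone (adjusted p = 4.75e-07; adjusted p = 0.369 with an estimated correlation), among them BMP6 (2.77 ± 0.34), RSPO2 (3.05 ± 0.51), WNT3A (2.53 ± 0.46) and MSX1 (2.26 ± 0.42). BMP, TGF-beta and NODAL targets rose in 4 of 17, 12 adjusted over the list alone (adjusted p = 7.56e-07; adjusted p = 0.369 with an estimated correlation), including TGFBI (3.23 ± 0.58), ID3 (2.21 ± 0.40) and NODAL (2.32 ± 0.41). HOX genes had none called of 16 and 14 higher adjusted over the list alone (median 3.68; adjusted p = 7.56e-07; adjusted p = 0.371 with an estimated correlation). PAX6 (-0.92 ± 0.13) and SOX1 (-0.52 ± 0.08) were the 2 called of 13 neuroepithelium genes, 4 adjusted over the list alone (adjusted p = 0.0338; adjusted p = 0.467 with an estimated correlation).

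Further single genes marked the same samples. By size the rises in Homo at day 30 were ORM2 (6.62 ± 1.08), the morphogen SHH (6.09 ± 1.21), WNT8B (5.82 ± 1.14), TF (5.39 ± 0.78) and CER1 (5.01 ± 0.93). The falls included ZNF267 (at least 316-fold), CHCHD2 (-7.90 ± 0.46), and the X-linked genes TKTL1 (-2.46 ± 0.30) and CHRDL1 (-2.43 ± 0.41). TBXT, a mesoderm factor, had 390 counts in Homo and 1 in controls, a ratio of 336 (60 to 13300). The liver and yolk sac gene AFP and TTR, a member of the choroid plexus list, reached 542.1 ± 74.7 and 151.3 ± 26.5 CPM in Homo (SD, n = 2). Controls had 46.4 ± 63.0 and 26.0 ± 28.3, a wide spread between the control lines. Neither gene passed (edgeR adjusted p = 0.333 and 0.337), and the reason was not tested. In edgeR 575 of 21481 genes were called at day 30, 481 higher and 94 lower, which is 83.7 percent higher, and 72.5 percent of 2424 with DESeq2. Without Parental the count was 33, without WT 0 (2732 at an unadjusted p under 0.05), without Het clones 1, 2 and 3 it was 3, 1 and 1021, and without Homo clones 1 and 2 it was 1328 and 5, so none of the named genes kept its call without each line.

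**Figure D5:**
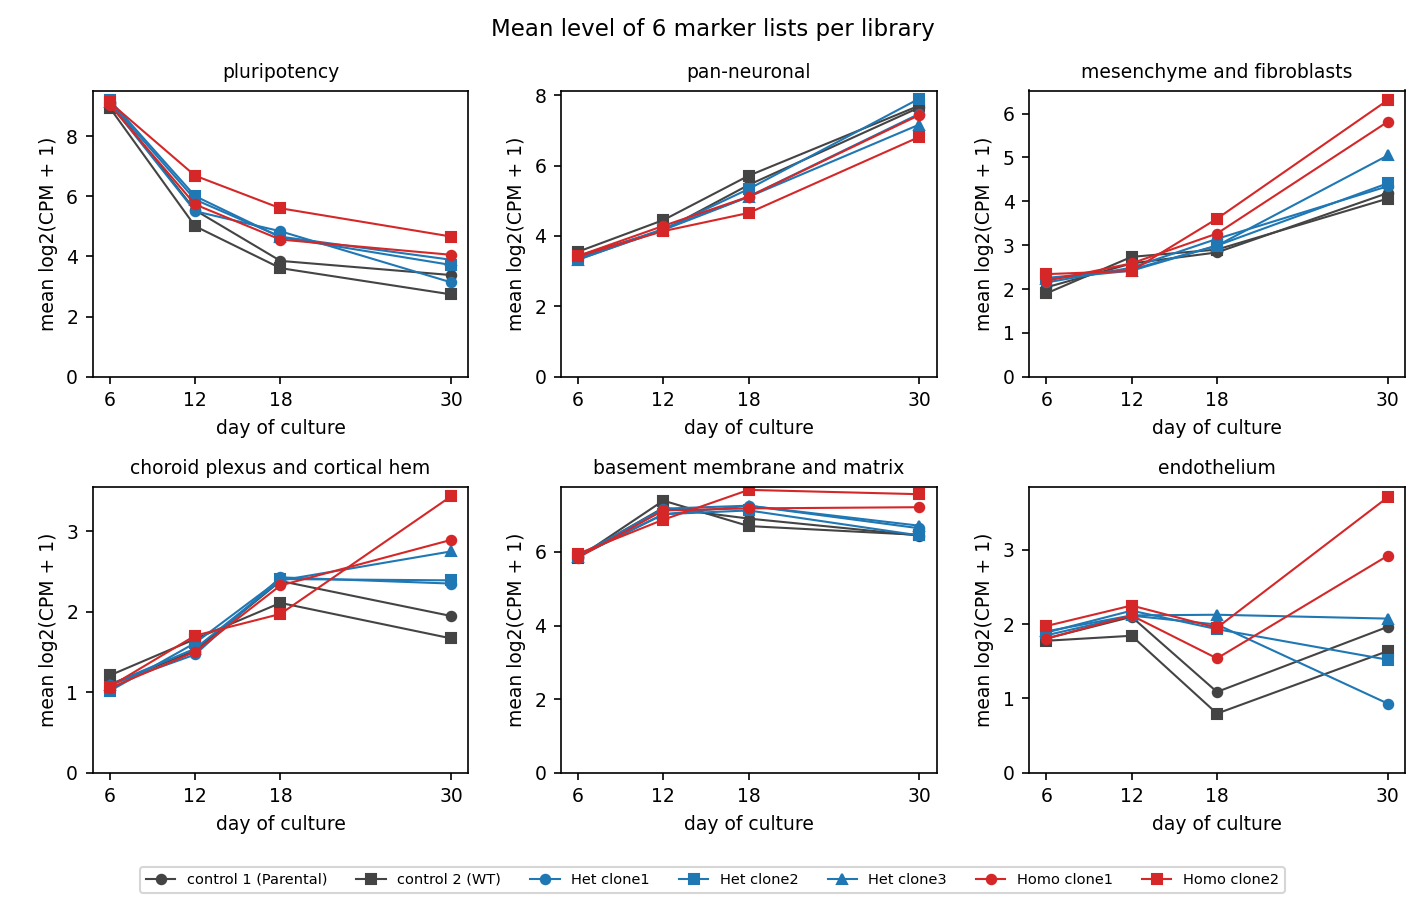
Mean log2(CPM + 1) over the members of 6 gene lists (vertical axes, from 0) against day of culture for each line, 1 point per library, with control lines in grey, Het clones in blue and Homo clones in red. At day 30 the Homo clones lie above the controls for mesenchyme, choroid plexus, matrix and endothelium, and at day 18 all mutant lines lie above the controls for pluripotency.

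In Het at day 30, 31 genes were called by edgeR, 16 higher and 15 lower (51.6 percent higher, and 68.8 percent of 560 with DESeq2), with 2182 at an unadjusted p under 0.05. CCNO, a regulator of multiciliated cells, rose by 5.12 ± 0.43 (adjusted p = 0.0302), to 4.12 ± 0.81 CPM (SD, n = 3) from 0.118 ± 0.042 (n = 2), and SPAG6, a gene of motile cilia, by 2.40 ± 0.26. MLXIPL (2.89), CALHM5 (2.08) and the calcium channel gene ITPR2 (1.62) rose as well, and CHCHD2 (-11.15), TKTL1 (-2.07), FGF7 (-1.60) and SPATC1L (-1.19) fell. Choroid plexus and hem genes had a median of 1.08 with none called of 19 and 10 adjusted over the list alone (adjusted p = 9.77e-06; adjusted p = 0.789 with an estimated correlation). The ventral telencephalon list was lower (median -0.75, none of 14 called; adjusted p = 0.000818; adjusted p = 0.789 with an estimated correlation). Ribosomal protein genes were lower by a small median of -0.19 (none of 27 called; adjusted p = 3.65e-06; adjusted p = 0.789 with an estimated correlation). DCN stood at 16.16, 16.22 and 25.25 CPM in Het clones 1, 2 and 3, above Parental (2.862) and WT (0.6337). LUM stood at 30.65, 31.52 and 44.6 CPM, above Parental (16.16) and WT (7.675). TF, at 0.4216, 0.8221 and 1.067 CPM, overlapped Parental (0.9971) and WT (0.8625). None of these genes was among the named rises in Het. PAX6 had a value of -0.79 ± 0.12 and did not pass (adjusted p = 0.0681). The count was 1 without WT, 1, 1 and 7 without Het clones 1, 2 and 3, 47 without Homo clone 1 and 51 without Homo clone 2.

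The change from day 6 to day 30 was itself compared between genotypes. In Homo, basement membrane and matrix genes changed more upward than in controls (8 of 17 called, 11 adjusted over the list alone; camera adjusted p = 8.6e-08; adjusted p = 0.101 with an estimated correlation), including COL4A1 (1.58 ± 0.28) and COL18A1 (1.27 ± 0.17). BMP, TGF-beta and NODAL targets had 6 of 17 called, 10 adjusted over the list alone (adjusted p = 4.8e-05; adjusted p = 0.0972 with an estimated correlation), including TGFBI (3.13 ± 0.57) and ID2 (1.47 ± 0.32). Pluripotency genes fell less than in controls (3 of 15 called, 10 adjusted over the list alone; adjusted p = 7.35e-07; adjusted p = 0.363 with an estimated correlation), and WNT targets had 3 of 18 called, 5 adjusted over the list alone (adjusted p = 0.000412; adjusted p = 0.0614 with an estimated correlation), such as NKD1 (1.43 ± 0.25). With line as a replicate block, imprinted genes (adjusted p = 0.0516, and 0.033 with the block) and pan-neuronal genes (0.0502, and 0.0336) also passed, both lower. These calls were lost otherwise (adjusted p = 0.365 and 0.488 with an estimated correlation). The edgeR test called 1057 genes, 667 higher and 390 lower. It called 581 without Parental, 69 without WT, 609 and 613 without Het clones 1 and 2, 2241 without Homo clone 1 and 176 without Homo clone 2.

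In Het the change over time was more positive for midbrain and hindbrain genes (1 of 20 called, PAX7 at 4.33 ± 0.86, and 4 adjusted over the list alone; adjusted p = 6.95e-06; adjusted p = 0.205 with an estimated correlation). Neuroepithelium genes had ZIC2 as the 1 called of 15 (1.72 ± 0.30; 5 adjusted over the list alone; adjusted p = 0.000679; adjusted p = 0.466 with an estimated correlation). The WNT feedback genes NKD1 (1.5 ± 0.23) and ZNRF3 (0.62 ± 0.13) were the 2 called of 18 WNT targets, 4 adjusted over the list alone (adjusted p = 0.00258; adjusted p = 0.132 with an estimated correlation). TNNT1 (2.21 ± 0.37), GAS1 (1.74 ± 0.32) and COL4A5 (1.26 ± 0.25) also changed more upward than in controls. COL4A5 was lower in Het than in controls at day 6, so its larger change need not mean a higher level at day 30. The edgeR test called 135 genes, 99 higher and 36 lower, and 206 with line as a replicate block. The count was 262 without Parental, 4 without WT, 11, 36 and 9 without Het clones 1, 2 and 3, and 348 and 341 without Homo clones 1 and 2.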

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

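The tests on genes near 0, on the ratio of Homo to Het, on single Homo clones, on the neural share and on GC content in lists other than mesenchyme were chosen only after the result was seen, as was the calibration on single control lines, while the tests on related loci, GC content in mesenchyme, delay and carry-over were written before.

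The change from day 6 to day 30 differed between mutant and control lines in the interaction test of edgeR, which drew 1057 genes in Homo and 135 in Het to closer attention. In Homo, ISM1, which encodes a secreted protein, had 168 counts against 177 in controls at day 6 and 231 against 1 at day 30. This is a ratio of 199 at day 30 (95 percent counting interval 35.4 to 7900; interaction adjusted p = 0.00078). TF changed by 6.075 more than in controls on the log2 scale (adjusted p = 0.0104) and stood at 37.7 ± 34.4 CPM at day 30 (SD, n = 2). ORM2 changed by 5.225 more (0.0076), IGF2 by 4.487 (0.0222) and NLRP7, a gene tied to maternal imprinting, by 4.213 (0.0331). The neuronal genes NRN1 (-3.449, adjusted p = 0.00596), LRRTM3 (-3.375, 0.0374) and SLITRK3 (-2.441, 0.0111) changed less upward or more downward than in controls, as did CHODL (-3.137, 0.00179) and CDKN1A (-2.429, 0.0088). NRN1 stood at 0.109 CPM in controls and 0.841 in Homo at day 6, and at 47.7 and 33.1 at day 30.

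In Het, ISM1 had 202 against 177 counts at day 6 and 85 against 1 at day 30, a ratio of 57.5 (10 to 2300; adjusted p = 0.0131). The midbrain and dorsal neural tube factor PAX7 changed by 4.33 more than in controls (adjusted p = 0.0295), CBLN1 by 3.837 (0.000768), NFIX by 3.73 (0.00371) and GREB1L by 3.635 (0.0376, and 0.0717 with line as a replicate block). PAX7 and GREB1L had lower mean levels at day 6, at 0.367 CPM in Het against 4.23 ± 3.81 in controls for PAX7 and 6.52 against 61.4 ± 53.3 for GREB1L (SD, n = 2), where the control lines varied widely. Lower changes than in controls were measured for NRN1 (-2.858, adjusted p = 0.0381), GCNT4 (-2.8, 0.0142), NTN4 (-2.001, 0.0308), B3GALT5-AS1 (-1.937, 0.027) and HS3ST3A1 (-1.85, 0.0121).

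The first pattern weighed was the set of genes near 0 in all mutant lines, CHCHD2, ZNF267, ZNF257, ZNF98, ZNF849P and ZNF492. Of 21 ways to set 2 lines apart, only 1, the control pair, had as many as 6 genes with a 4-fold gap on every day, but that rule was set on genes already seen, so a chance division of the lines stays open. A move of counted reads from CHCHD2 to its 10 relatives is excluded, since these gained -3.35 percent of what it lost. Reads discarded in counting because they match several loci would not appear there, so such a loss stays open. For the chromosome 19 zinc finger genes a move of reads to related loci stays open, because their 295 relatives moved by -295 percent of the loss. ZNF267 was not tested. The CBP genotype stays open, and so could a difference between control and mutant lines that arose in culture or cloning: the median Homo to Het ratio of 1.03 comes from 219 genes chosen for their call in Het, which decides nothing about dose.

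The second pattern was the higher non-neural lists in Homo at day 30. A single Homo clone is excluded as the only source for mesenchyme, whose median was at least 1.526 without either clone, and without clones 1 and 2 the medians were 3.351 and 2.713 for endoderm and 0.9509 and 0.7968 for neural crest. A lower neural share that raises every other cell type alike is excluded as the whole cause: endoderm (3.06, 2.349 to 4.577 without 1 line) and neural crest (0.98, 0.7968 to 0.9936) lay at least 1.42 apart in each fit, a pair picked from 7 lists after these were seen. A trend with GC content or gene length is excluded, since its removal shifted genes by at most 0.283, with medians of 1.77 for mesenchyme (1.81 before), 3.03 for endoderm (3.06 before) and 0.991 for neural crest (0.981 before). More cells of mesenchymal and other non-neural types, or a higher expression of their genes, may both underlie the pattern, and counts of whole organoids do not separate them.

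The third pattern was the higher pluripotency transcripts in mutant lines at day 18. Delay along the control time course stays open, because the smallest excess over the level expected from position was 0.455 (Het clone 3) and the largest 1.76 (Homo clone 2). Carry-over of day 6-like cells also stays open: at least 92.5 percent of 80 genes that had fallen 100-fold in controls lay above the control mean in each mutant line, but a delay could raise such genes too. As a calibration, genes chosen on 1 control lay above it in 47.6 or 68.3 percent of cases in the other control, and in 90.5 to 100 percent and 93.9 to 98.8 percent of cases in the mutants. The rise could therefore reflect late loss of pluripotent cells, slower progress of all cells, or both.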

How the results depend on the processing

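The tests without chromosome X and those with separate control lines were chosen only after the result was seen, and all others before the data were read. Of 761 called results of described genes, 0 reversed over 15 settings, 224 kept their call in every setting and 264 without each line in turn. RLE factors moved no count of calls over 1.5-fold. For the values that moved, the cause was not tested. Leaving out a line left some arms with 1 line, which was assumed to vary like the others. In simulated counts with known changes, edgeR found 94 of 100 changes of 2-fold in the Homo sums and 96 at day 6. It found 44 at day 30 and 53 in the change over time, so absent calls show least in the last pair. In the sums, at day 6 and at day 30, unchanged genes took a larger share of the simulated calls than the adjustment aims for. Genes under about 10 counts were mostly outside the tests.

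Counts of called genes moved as follows against the edgeR values. In the summed time course, limma-trend gave 6 for Homo against Het (109 in edgeR). In limma-voom with line as a random effect there were 4538 for Homo (2880), 817 for Het (292), 464 for Homo against Het and 1426 for any mutant (250). The correlation within a line estimated in that fit was -0.0287 with the genotypes apart and 0.0207 for any mutant. The block thus had almost no effect, and the days of a line entered nearly as separate replicates. All libraries in a single fit gave 322 and 222 at day 6 for Homo and Het (1476 and 978), and 403 for Het at day 12 (618). It gave 2411 and 463 at day 18 (212 and 82), and 3995 and 517 at day 30 (575 and 31). DESeq2 gave 4554, 1296, 1533 and 2007 for Homo, Het, Homo against Het and any mutant in the sums, and 1478 and 1714 for Het at days 6 and 12. At day 18 it gave 2281 and 840, at day 30 it gave 2424 and 560, and it gave 1993 and 587 for the change from day 6 to day 30 (1057 and 135). Without a filter on low counts, the sums gave 648 for Het, 631 for Homo against Het and 438 for any mutant. Day 6 gave 2234 and 1823, and day 12 gave 4333 and 2350 (2686 in Homo with the filter). Day 18 gave 1365 and 564, day 30 gave 1607 and 318, and the change over time 2294 and 1004. Without genes of chromosome X, Het had 51 calls at day 18 and 2 at day 30.

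Leaving out each line in turn, the sums ranged from 153 to 6034 for Homo, 64 to 1016 for Het, 0 to 3671 for Homo against Het (edgeR, with 2940 genes at an unadjusted p under 0.05 at the lowest) and 44 to 1231 for any mutant. Day 6 ranged from 283 to 1642 in Homo and 235 to 1411 in Het, day 12 from 985 to 4731 and 61 to 1988, day 18 from 2 to 6856 and 2 to 1691, and day 30 from 0 (2732 unadjusted) to 1328 and 1 to 51. The control change ranged from 13105 to 16873, the Homo change from 69 to 2241 and the Het change from 4 to 348.

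The labels name the line of each library. The main fits over days had no block, and line entered as a replicate block in an alternative fit. With the block, the Het change over time had 206 calls (135 without it), the Homo change 1275 and the control change 16321, and the imprinted and pan-neuronal lists were called in the Homo change (adjusted p = 0.365 and 0.488 with an estimated correlation, and 0.0655 and 0.185 with fry). With the block, 4 described genes lost their call, KRT19 (adjusted p = 0.0502) and VWF (0.0587) in the Homo change and GREB1L (0.0717) and ID2 (0.0651) in the Het change. The pairing changed no other call of the described genes and lists.

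Of 581 gene list tests, camera called 185, 1 with an estimated correlation, 65 with fry, and 138 to 213 without 1 line. Without some line 86 of the 185 were lost, and 0 reversed. The overlap of Homo and Het calls was 255 genes with both control lines, 68 with Parental alone, and 88 and 75 with separate control lines.

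Signs reversed only for CREBBP and EP300, each in comparisons where that gene itself was not called, and the cause was not tested. EP300 at day 30 in Het was -6.658e-05 without the filter. Leaving out single lines, EP300 ranged from -0.1233 to 0.03142 (Homo) and -0.07741 to 0.07762 (Het) in the sums, and from -0.2102 to 0.06694 and -0.209 to 0.0687 at day 6. It ranged from -0.03093 to 0.123 in Homo at day 12, from -0.1188 to 0.01502 and -0.1058 to 0.02835 at day 18, and from -0.3471 to 0.02599 and -0.08283 to 0.08787 at day 30. CREBBP ranged from -0.3825 to 0.01887 in Homo and -0.0665 to 0.02238 in Het at day 18, and from -0.09068 to 0.1429 in Het at day 30. CREBBP in the Homo sums (-0.23) ranged from -0.2987 to -0.161.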

Other observations

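The tests of chromosomes were chosen only after the result was seen, and the test of other groupings of lines before. Clustered beta protocadherins, adhesion genes whose choice of promoter varies between cell clones, were lower in the Homo sums (1 of 16 higher and 2 lower, 1 and 7 adjusted over the list alone; camera adjusted p = 0.00256; adjusted p = 0.622 with an estimated correlation). PCDHB16 changed by -1.09 ± 0.23 and PCDHB12 by -0.55 ± 0.13, while PCDHB5 rose by 0.47 ± 0.09 in Homo and 0.79 ± 0.08 in Het. In controls 12 of the 16 rose between day 6 and day 30 and 1 fell (adjusted p = 0.00495; adjusted p = 0.309 with an estimated correlation). The maternally expressed H19 and the paternally expressed IGF2, neighbours on chromosome 11, both rose in the Homo sums, by 2.58 ± 0.52 and 2.32 ± 0.46.

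Genes of chromosome X were called more often than those of other chromosomes in Het. Among genes with a mean log2 CPM of at least 1, 5.72 percent of 542 on chromosome X were called in the Het sums, against 0.735 to 2.21 percent on each other chromosome, and in Homo 20.85 percent against 10.96 to 18.16. More were lower than higher, with 24 lower and 7 higher in Het and 79 and 34 in Homo. Named members were COL4A5, CHRDL1 (-1.36 at day 6 in Homo and -1.18 in Het) and TKTL1 (-1.53 ± 0.18 in the Homo sums and -1.34 ± 0.16 in the Het sums).

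With any other 5 of the 7 line sums set against the remaining 2, 1 grouping called more genes than the real one, the 2 Homo lines against the rest with 408 against 250. As 2 of 21 groupings were thus at least as large, the count of 250 alone cannot exclude a chance division of the lines, although the larger grouping is itself one by genotype.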
